A study of Mus musculus with 16 samples.

How the data were processed

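RNA sequencing of 16 libraries of cultured mouse cells was analysed in 6 groups taken from the labels: ESC, 2C-like cells, bTSC, iTSC lines C1 and C2, and DuxKO iTSC. The submitters' labels gave polyA RNA for the 4 ESC and 2C-like libraries and total RNA for the 12 TSC libraries. By their labels the 2C-like cells had received NaB at 0.5 mM over 2 days. The share of counts in ribosomal RNA rows was higher in the libraries labelled polyA RNA, the reverse of what poly(A) selection gives. These rows were chosen after the table had been opened, and include rows annotated otherwise, such as Mir6236 and Lars2. The treatment text of the ESC samples mentions the same treatment although their titles do not. The labels do not say whether the numbered libraries were separate cultures, so each line counts as 1 line and the tests measured the spread between its libraries.

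The values deposited by the authors were expected counts per gene, that is estimated counts with decimals and without scaling, in 1 table of 55304 rows. Per the submitters' processing notes the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.5a and HTSeq 0.13.5 on the genome build mm10. The step that gave decimals is not stated. Counts were rounded to whole numbers for the tests. For gene positions and types, 53462 rows were matched to 1 gene name of GENCODE M21 and 1842 were not. Near-identical gene copies, such as those of the Zscan4, Usp17l, Tdpoz, Rhox and histone families, were taken as listed.

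Total counts were 23492727 and 22737471 in ESC, 16478454 and 12444696 in 2C-like cells, 21315447 and 22673998 in bTSC, and 22083096 and 19281836 in DuxKO iTSC. Line C1 had 23194712, 18076514, 15880338, 3672418 and 20317187 counts in libraries 1 to 5, and line C2 had 19494853, 19729252 and 20373356. CPM were computed with library sizes scaled by TMM. A gene at 0 in a group was given a fold bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% counting interval. Intervals of shares were computed by the Wilson method. All intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

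Tests were run in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM, a robust quasi-likelihood fit and its F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. For 2C-like cells against ESC the 4 libraries were fitted alone. TSC groups were compared with ESC in a fit of all 16 libraries, and with each other in a fit of the 12 TSC libraries. The NaB iTSC value was the mean of lines C1 and C2 on the log scale with equal weight. No replicate number was used as a block, because the labels do not state a pairing.

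Chromosome-wide levels used log2(CPM + 1) of autosomal protein-coding genes at a mean of 5 CPM or more over the TSC libraries, with bins of 10 Mb.

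The 19 gene lists covered pluripotency, the 2-cell stage, TSC self-renewal, differentiated trophoblast, primitive endoderm, fibroblast or feeder cells, primed epiblast, somatic germ layers, germline, imprinted genes, FGF/ERK feedback, p53 targets, interferon response, the deacetylase family, glycolysis, sterol synthesis, G2/M of the cell cycle, mitochondrial transcripts and RNAs without a poly(A) tail. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and the same adjustment. Of 152 list tests 66 were past the threshold at the preset correlation and 7 with the estimated one. The 7 were TSC self-renewal in NaB iTSC against ESC, primed epiblast, imprinted genes and G2/M in DuxKO iTSC against NaB iTSC, G2/M in DuxKO iTSC against bTSC, and primitive endoderm and imprinted genes in C2 against C1.

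Genes were named by a rule. It took the 10 largest rises and the 10 largest falls per comparison among called genes at 10 CPM or more in the higher group, without symbols that are only model names. It took up to 4 called members of each list with the lowest adjusted p. It always took Zscan4c, Zscan4d, Zfp352, Duxf3, Tcstv3, Pou5f1, Sox2, Nanog and Cdx2 in 2C-like cells against ESC, and Cdx2, Eomes, Elf5, Tfap2c, Gata3, Esrrb, Sox2, Pou5f1, Nanog and Zscan4c in the TSC comparisons. Comparisons, tests, lists and this rule were fixed before the data were examined.

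The alternatives set in advance were DESeq2 1.42.0, DESeq2 size factors within edgeR, no low-count filter, no fold threshold, each library left out in turn, the replicate number as a block, another set of libraries in the fit, the 8 NaB iTSC libraries as 1 group, the line as the unit, and the estimated correlation. In fits that held line C1 the block also set C1 libraries 4 and 5 aside, since no other group has these numbers. Removal of ribosomal RNA rows, protein-coding genes only without histone and mitochondrial genes, C1 libraries 1 to 3 only and C1 libraries 4 and 5 only were chosen after seeing the data. Each comparison was tested on simulated data with the same sizes and spread. Of the simulated genes 200 were changed, and every other gene had 1 mean in all groups. The simulation therefore does not cover scaling error where many genes change, or differences among the libraries of line C1. Its percentages cover changed genes that passed the low-count filter. Of genes changed by a log2 value of 2, between 78 and 93% were called, of genes changed by a value of 1, at the threshold, between 31 and 48%, and of unchanged genes 1 to 6 were called per comparison, but 21 in 2C-like cells against ESC. The deposited submission form and its list of raw data were left out because they hold no measurement.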

Results

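The 16 libraries came from mouse cells in 6 groups. There were 2 libraries of GFP-negative embryonic stem cells (ESC) and 2 of GFP-positive cells sorted after sodium butyrate (NaB), labelled 2C-like after the 2-cell embryo. The trophoblast stem cells (TSC) comprised 2 libraries of a blastocyst-derived line (bTSC), 5 and 3 libraries of the NaB-induced lines C1 and C2 (NaB iTSC), and 2 of an induced line labelled as a Dux knockout (DuxKO iTSC). Total counts per library ran from 3672418 in C1 library 4 to 23492727 in ESC library 1, and a floor of 3 counts corresponded to 0.114 to 0.731 CPM (counts scaled to library size). The question was how closely the induced lines resembled bTSC and how the knockout line differed.

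Dux, the transcription factor that drives the cleavage-stage programme, was listed in the table as Duxf3, on chromosome 10 from 58229979 to 58232675 of mm10. It was at 0 in both ESC libraries and at 7.12 and 6.14 CPM in the 2C-like libraries. In the TSC it was at 0 in both bTSC and both DuxKO libraries. Line C1 held 1 count in library 1 and 4 counts in library 3 and none in libraries 2, 4 and 5, and line C2 held 1 count in library 3 and none in the others. The difference of NaB iTSC minus DuxKO, with NaB iTSC taken here as the mean of its 8 libraries, was 0.0378 CPM, or 0.0117 CPM without C1 library 3, under the floor of 3 counts, so loss of Dux was not detectable at this depth.

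Genes of the cleavage-stage programme were higher in the 2C-like cells than in ESC. Of the 33 tested members of the 2-cell-stage list, 32 were higher than in ESC and none was lower (32 also when adjusted over the list alone). Zscan4c, a telomere-associated factor of the 2-cell embryo, averaged 80.7 ± 14.7 CPM (SD, n = 2) and was at 0 in ESC, which makes it at least 1197-fold higher. Zscan4d was at least 1073-fold, Zscan4b at least 532-fold, Zscan4a at least 510-fold and Usp17lc at least 267-fold higher. The further members Zfp352, Tcstv3 and Duxf3 were at least 73.8-fold, 88.2-fold and 98.3-fold higher. These families have many near-identical copies, and reads shared between copies were not separated.

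Of the germline genes, 22 of 28 tested were higher and none lower (22 adjusted over the list alone). Mael, of the piRNA pathway, rose by a log2 change of 3.07 (SE 0.14) and Tex19.1, a germline genome defence gene, by 2.41 (SE 0.10). Meioc, needed for meiosis, rose by 2.60 and Mov10l1 by 2.31. The pluripotency list was little changed, with 1 of 30 higher and 2 lower (the same counts adjusted over the list alone). Pou5f1 was at −0.51 (SE 0.08), Nanog at 0.49 (SE 0.07) and Sox2 at 0.08 (SE 0.07), and none of the 3 was called. Dppa3, a maternal factor, rose by 1.91, while Gdf3 was at −2.15 and Tcl1 at −1.19.

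The strongest falls were in Nodal antagonists. Lefty2 was at −6.33 (SE 0.20) and Lefty1 at −5.70 (SE 0.13), from 97.2 CPM in ESC to 1.75 CPM. Ak7 was at −3.16, Pax6, a neural factor, at −3.04 and Patl2 at −2.90. In glycolysis 4 of 20 genes were lower and none higher, among them Tpi1 at −1.29 (SE 0.08) and Ldha at −1.13 (SE 0.08). The fibroblast list was higher for 7 of 11 tested genes, with Col1a1 at 6.43 against 0.27 CPM and Col5a1 at 23.2 against 5.55 CPM. Among imprinted genes 7 of 34 were higher and 3 lower, with Peg10 up by 1.84 and H19 by 2.31, and Grb10 at −1.25. Of the RNAs without a poly(A) tail, a list that also holds histone messages, 3 of 11 were higher. The noncoding RNA Rmrp was at least 61.6-fold higher. The share of counts in ribosomal RNA rows (95% Wilson intervals at most 0.0513 percentage points wide) was 45.9 and 69.3% in the 2C-like libraries against 18.5 and 16.98% in ESC.

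**Figure D1:**
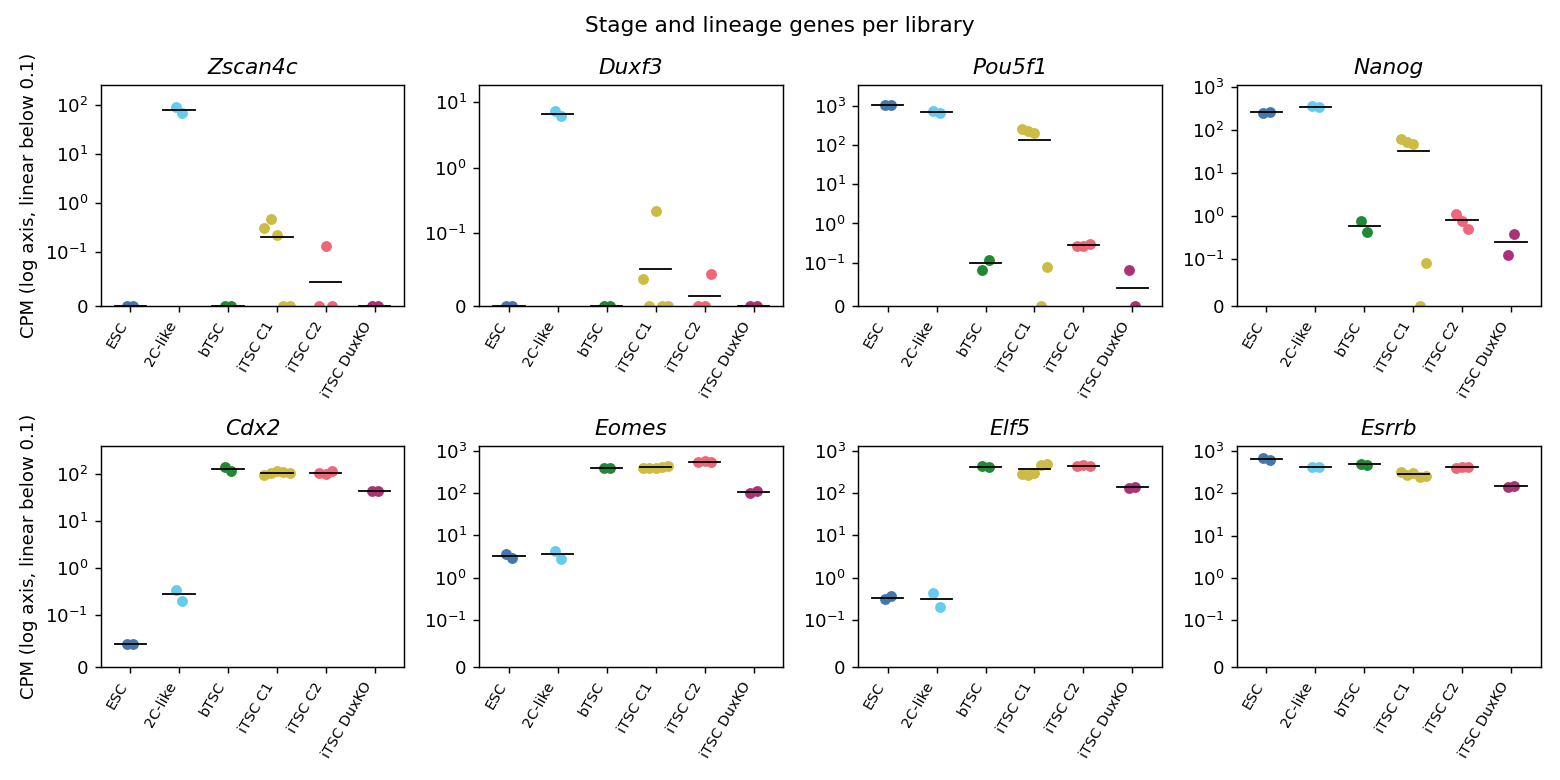
CPM of 8 stage and lineage genes per library, on an axis that is logarithmic above 0.1 and linear below, with 1 point per library and a bar at each group mean. Zscan4c and Duxf3 stood out in 2C-like cells, and Pou5f1 was between 195 and 251 CPM in libraries 1 to 3 of line C1 and at 0 and 0.0908 CPM in libraries 4 and 5.

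By edgeR quasi-likelihood tests 2719 of 16905 genes were called, 2049 higher and 670 lower. The camera test gave an adjusted p of 8.27e-136 for the 2-cell-stage list (0.297 as the adjusted p with an estimated correlation), 1.99e-22 for germline (0.501), 2.04e-05 for fibroblast (0.612), 6.65e-05 for glycolysis (0.612) and 0.00366 for the RNAs without a poly(A) tail (0.612). The calls of Gdf3, Tcl1, Dppa3 and Col1a1 ended when all 16 libraries were fitted together, with values of −2.19 (SE 1.55), −1.24 (SE 1.32), 1.84 (SE 1.2) and 4.58 (SE 1.99). The treatment text of the ESC labels also mentions NaB although their titles do not, so whether the GFP-negative cells had received it is unclear.

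**Figure D2:**
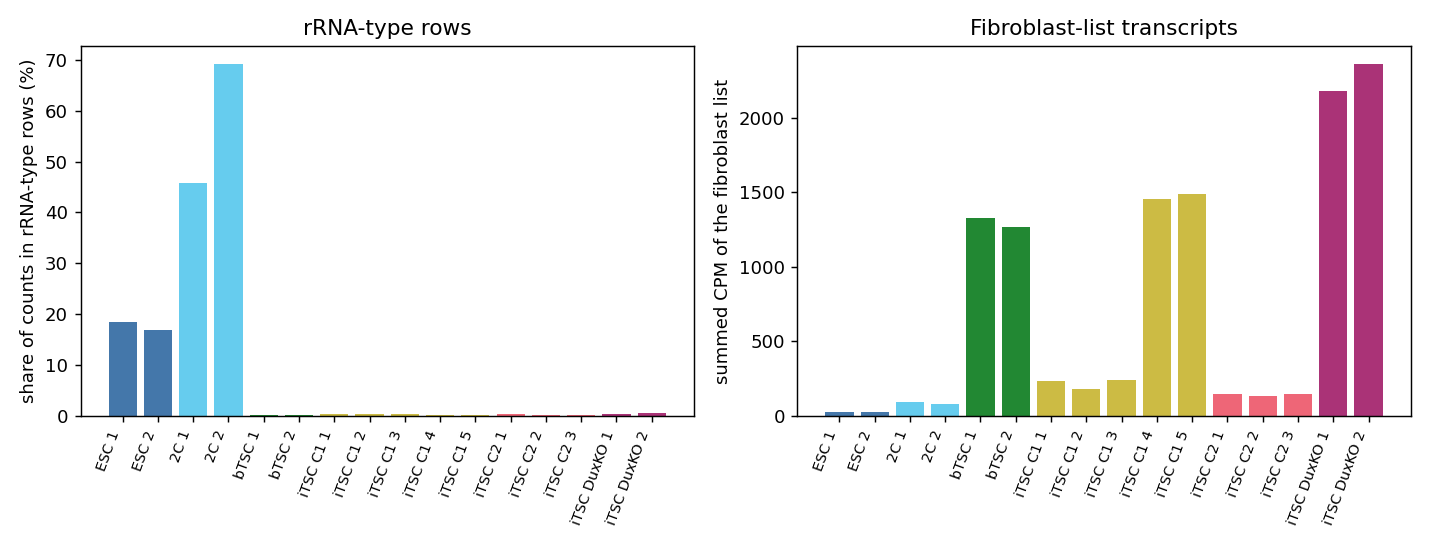
Share of counts in ribosomal RNA rows (left, percent) and summed CPM of the fibroblast list (right), with 1 bar per library. The ribosomal share reached 69.3% in 2C-like library 2 and stayed at or below 0.592% in all TSC libraries, and fibroblast-list transcripts summed to 1457 and 1487 CPM in C1 libraries 4 and 5 against 183 to 243 CPM in C1 libraries 1 to 3.

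The NaB-induced lines had higher levels of trophoblast stem cell genes and lower levels of most pluripotency genes than ESC. Of 30 genes of TSC self-renewal, 28 were higher than in ESC and none was lower (28 adjusted over the list alone). Cdx2, a master factor of the trophectoderm, was at 106 CPM against 2 counts in ESC, a ratio of 2347 (95% counting interval 650 to 19380). Elf5, which reinforces the trophoblast fate, averaged 396 CPM against 0.338 CPM and Eomes 475 against 3.30 CPM. Tfap2c rose by 4.46 (SE 0.10), Gata3 by 128-fold and Tinagl1 by 9.99 (SE 0.19).

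The pluripotency list was lower for 25 of 30 genes and higher for none (25 adjusted over the list alone). Tet2 was at −2.79 (SE 0.07), Klf2 at −3.23 (SE 0.10), Zfp42 at −2.36 (SE 0.09) and Tbx3 at −1.96 (SE 0.13). Pou5f1 was at −7.35 (SE 1.42) and Nanog at −5.65 (SE 1.04), and libraries 1 to 3 of C1 held 195 to 251 CPM of Pou5f1. Esrrb (−0.94) and Sox2 (−0.61), factors shared by both stem cell types, were not called. Imprinted genes split, with 15 of 35 higher and 13 lower, and Igf2, the fetal growth factor, rose by 10.21 (SE 0.21) to 3040 CPM.

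Differentiated trophoblast genes were mixed, with 11 of 29 higher and 4 lower. Hand1, a giant-cell factor, rose by 10.02 (SE 0.44) and Flt1 by 7.19 (SE 0.17). In the 2-cell-stage list 3 of 33 genes were lower and none higher (1 lower adjusted over the list alone). Duox2, an oxidase gene, was at least 2264-fold higher, and Tnc, a matrix gene, at least 1844-fold, with 568 and 572 CPM in C1 libraries 4 and 5 and at most 20.4 CPM in the other 6 libraries. Rhox4g was at least 717-fold higher, Kcnk13 at least 667-fold and Tmem114 at least 517-fold. Fibroblast-list genes were higher for 21 of 25, p53 targets for 16 of 24 with 1 lower (Perp by 5.24, SE 0.20) and sterol synthesis genes for 9 of 23 with 1 lower (Sqle by 1.42, SE 0.08).

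The largest falls were in noncoding RNA and histone rows. Mir6236, annotated as a microRNA and counted here among the ribosomal RNA rows, was at −15.37, and the ribosomal RNA row n-R5-8s1 was at 0 in NaB iTSC, at least 1682-fold lower. Hist1h2ao, a replication histone, was at least 13050-fold lower. Bc1, a neuronal noncoding RNA, had 1 count in the 8 libraries, so ESC exceeded it by a ratio of 8153 (95% counting interval 1462 to 322100). The mitochondrial serine tRNA mt-Ts1 was at −11.84 and Rn7sk at −10.25. Mitochondrial messages were lower for 5 of 13 genes, but their sum was not lower. It was 21310 to 22930 CPM in C2 and C1 libraries 1 to 3, and 16600 and 18080 CPM in C1 libraries 4 and 5. In ESC it was 15680 and 19060 CPM. The deacetylase family moved both ways, with 3 of 18 higher and 3 lower. The ESC libraries were labelled polyA RNA and the TSC libraries total RNA, but ribosomal RNA rows held 16.98% of counts or more in the former and at most 0.592% in the latter, the reverse of what poly(A) selection gives, so the kind of library is uncertain and cannot be told apart from the cell type. Of the genes with a count, 39.8 to 50.2% had decimals in the ESC and 2C-like libraries and 14.6 to 22.2% in the TSC libraries, and rows named as pseudogenes summed to 13090 to 17600 and 2379 to 3476 CPM. A difference in alignment or counting between the 2 sets is therefore not excluded, and the fall of a row at 0 in all 12 TSC libraries, such as Hist1h2ao, cannot be read as expression alone.

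Of 19457 genes 9422 were called by edgeR, 4105 higher and 5317 lower. Adjusted camera p values were 2.90e-36 for TSC self-renewal (0.0124 as the adjusted p with an estimated correlation), 1.40e-05 for pluripotency (0.460), 9.18e-06 for p53 targets (0.320), 0.00124 for sterol synthesis (0.460), 0.00866 for fibroblast (0.640), 0.0341 for FGF/ERK feedback (0.320) and 0.0180 for RNAs without a poly(A) tail (0.460). Restricting the table to protein-coding genes turned the share of called genes that were higher from 43.6 to 52.2%, and with the line as the unit edgeR called 4897 genes, 55.3% of them higher. The calls of Tnc and n-R5-8s1 ended when either ESC library was left out, with log2 values of 12.88 and 12.89 for Tnc and −12.08 and −12.44 for n-R5-8s1, which also ended with the replicate block at −12.38, that of Pou5f1 ended at −3.61 with the 8 libraries weighted equally, and with the line as the unit those of Tnc, Pou5f1, Nanog, Klf2 and Tbx3 ended at 15.29, −3.57, −3.60, −2.69 and −1.64.

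The other TSC lines were also compared with ESC. In bTSC 28 of 30 TSC self-renewal genes were higher and 24 of 30 pluripotency genes lower (29 and 24 adjusted over the list alone). In DuxKO iTSC these counts were 26 and 27, also when adjusted over the list alone. Cdx2 was at 130 CPM in bTSC and 43.0 CPM in DuxKO iTSC against 2 counts in ESC, ratios of 2891 (95% counting interval 800.0 to 23880) and 956 (264 to 7902). Elf5 was at 411 ± 13.04 CPM in bTSC and 137 ± 3.65 CPM in DuxKO iTSC. Pou5f1 was at 0.101 CPM in bTSC and at 0.0417 CPM in DuxKO iTSC, where 2 counts were left.

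Fibroblast-list genes were higher than in ESC for 23 of 25 in bTSC and for all 25 in DuxKO iTSC, with summed levels of 1270 to 1329 and 2181 to 2365 CPM. Interferon-response genes were higher for 13 and 18 of 21. Cell-cycle genes of G2/M were lower for 3 of 22 in bTSC and 18 of 22 in DuxKO iTSC, where the spindle checkpoint gene Bub1b was at −2.13 (SE 0.10). Esrrb was called lower in DuxKO iTSC, at −2.14 (SE 0.12), and was at −0.43 (SE 0.11) in bTSC, a difference of −1.70 (SE 0.12) when DuxKO iTSC was tested against bTSC. Primitive endoderm genes moved both ways, with 15 of 24 higher in each and 5 lower in bTSC and 4 lower in DuxKO iTSC.

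Compared with ESC by edgeR, 9503 genes were called in bTSC (4153 higher, 5350 lower) and 10562 in DuxKO iTSC (5057 higher, 5505 lower). For TSC self-renewal the adjusted camera p was 1.56e-19 in bTSC and 6.30e-17 in DuxKO iTSC (0.0849 and 0.0583 as the adjusted p with an estimated correlation), and for G2/M in DuxKO iTSC it was 2.56e-09 (0.0583). Pluripotency, differentiated trophoblast, primitive endoderm, fibroblast, p53-target and interferon-response genes were also past the camera threshold in both, as were RNAs without a poly(A) tail in bTSC and germline and sterol synthesis genes in DuxKO iTSC, and no list was past it with an estimated correlation. The kind of library, the way of counting and the cell type cannot be told apart in these comparisons either. With protein-coding genes only, the share of called genes that were higher turned from 43.7 to 54.8% in bTSC and from 47.9 to 53.3% in DuxKO iTSC.

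The core TSC factors differed between the NaB-induced lines and bTSC by less than the fold threshold. Cdx2 (−0.29, SE 0.09), Eomes (0.30, SE 0.07), Elf5 (−0.06, SE 0.22), Tfap2c (−0.49, SE 0.07), Gata3 (−0.30, SE 0.12), Esrrb (−0.50, SE 0.09) and Sox2 (−0.44, SE 0.31) were all below the fold threshold. Their levels in bTSC were 130 CPM for Cdx2, 382 CPM for Eomes and 411 CPM for Elf5. The pluripotency factors Pou5f1, at 5.87 (SE 4.06), and Nanog, at 3.11 (SE 1.99), were not called, with 195 to 251 and 48.3 to 61.6 CPM in C1 libraries 1 to 3 and at most 0.118 and 0.749 CPM in bTSC, and with C1 libraries 4 and 5 only Nanog turned to −1.29. Nanog held 0 and 2 counts in those C1 libraries, under the floor, so −1.29 is no exact fold. Within the wider TSC self-renewal list, 7 of 30 genes were lower and none higher (8 lower adjusted over the list alone). These included Krt7, a trophoblast keratin, at −1.88 (SE 0.13), Rhox9 at −5.16 (SE 0.18), Ets2 at −1.68 (SE 0.13) and the placental cadherin Cdh3 at −1.27 (SE 0.10).

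Differentiated trophoblast genes were lower for 10 of 28 and higher for none (10 adjusted over the list alone). Phlda2, an imprinted brake on placental growth, was at −6.83 (SE 0.31), with 14.1 CPM in C1, 0.0760 CPM in C2 and 123 CPM in bTSC. Cdkn1c, an imprinted cell-cycle inhibitor, was at −3.11 (SE 0.16), but at 92.9 CPM in C1 and 1.25 CPM in C2 against 93.1 CPM in bTSC. Fibroblast-list genes were lower for 11 of 25 (15 adjusted over the list alone), with Pdgfrb at −2.61 (SE 0.27), Tagln at −2.02 (SE 0.12) and Acta2 at −3.09 (SE 0.51). Summed fibroblast-list levels were 133 to 148 CPM in C2 and 1457 to 1487 CPM in C1 libraries 4 and 5. Primitive endoderm genes were lower for 5 of 23 and higher for 1.

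In the list of FGF/ERK feedback, which restrains growth-factor signalling, 7 of 18 genes were higher and 2 lower (the same counts adjusted over the list alone). The adjusted camera p with an estimated correlation was 0.303. Dusp6 was up by 2.27 (SE 0.18), Spry1 by 1.51 (SE 0.24) and Egr1 by 3.08 (SE 0.55). Sterol synthesis genes were higher for 6 of 23 and lower for none, among them Sqle by 1.16 (SE 0.08), Hmgcr by 1.26 (SE 0.13) and Hmgcs1 by 1.35 (SE 0.16). Primed epiblast genes were higher for 4 of 15, including Sox3 by 2.44 (SE 0.23), and p53 targets for 4 of 24 with 1 lower, including Psrc1 by 1.39 and Sesn2 by 1.41. Peg3, a paternally expressed gene, rose by 1.98, while Grb10 was at −1.12, and 7 of 35 imprinted genes were higher and 8 lower.

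The largest rises were in Zfp966 (5.49), Zic3 (5.21), Synpo2l (5.17), the glucose carrier Slc2a3 (5.12) and Insm1 (5.07). After Phlda2 the largest falls were in Ednra (−6.11), Trim9 (−5.96), the glycosyltransferase B3gnt3 (−5.43) and Tmem59l (−5.21). The Y-linked gene Eif2s3y was at 49.3 CPM in NaB iTSC and 1.85 CPM in bTSC, and Xist, the X-inactivation RNA, at 34.7 and 1016 CPM.

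By edgeR 2713 of 16655 genes were called, 1342 higher and 1371 lower. The bTSC were 1 line that differed in Eif2s3y and Xist, and its chromosomes 8 and 11 stood at log2 0.39 and 0.38 against line C2. An effect of induction cannot be told apart from such differences in sex-linked genes, chromosome-wide levels or origin of the line. Adjusted camera p values were 1.36e-05 for sterol synthesis (0.418 as the adjusted p with an estimated correlation), 8.40e-05 for fibroblast (0.588), 1.83e-04 for TSC self-renewal (0.455), 2.20e-04 for differentiated trophoblast (0.382), 0.00114 for FGF/ERK feedback (0.303), 0.00506 for p53 targets (0.601), 0.0358 for primitive endoderm (0.303), 0.0237 for glycolysis (0.713), 0.0242 for G2/M, which was lower (0.478), and 0.0242 for primed epiblast (0.382). With the line in place of the library as the unit edgeR called 0 genes, with 3979 at an unadjusted p under 0.05, DESeq2 on the same sums called 1033, and with the 8 libraries weighted equally 56.6% of called genes were higher, against 49.5%. The share of called genes that were higher went the other way in further settings, to 38.9% with C1 libraries 4 and 5 only and 44.1% without ribosomal RNA rows. With the 8 libraries weighted equally the call of Cdkn1c ended at −0.68 (SE 1.37), and those of Pdgfrb, Tagln and Acta2 ended at −1.84 (SE 0.73), −1.22 (SE 0.74) and −2.29 (SE 0.84), still past the fold threshold, and C1 libraries 4 and 5 alone turned Elf5 to 0.08.

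The Dux knockout line had lower levels of several core TSC factors than the NaB-induced lines. Eomes was at −2.14 (SE 0.08), from 475 to 107 CPM, Cdx2 at −1.30 (SE 0.10), Elf5 at −1.52 (SE 0.24), Esrrb at −1.20 (SE 0.10) and Sox2 at −1.54 (SE 0.36). Tfap2c at −0.90 and Gata3 at −0.13 were not called. The TSC self-renewal list split, with 9 of 30 genes higher and 8 lower (the same counts adjusted over the list alone). Bmp4, a growth factor gene, was at −1.57 (SE 0.07), whereas Krt7 rose by 2.93 (SE 0.13) and Rhox9 by 4.42 (SE 0.18).

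Differentiated trophoblast genes were higher for 14 of 28 and lower for 1 (the same counts adjusted over the list alone). Ctsj, a placental cathepsin, was at 12.04 CPM against 0.155 CPM, and Nrk rose by 3.74 (SE 0.31). The related cathepsin Ctsr was at 0 in NaB iTSC and at least 101-fold higher. Primitive endoderm genes were higher for 9 of 23 and lower for 1, with Gata6, an endoderm factor, up by 2.05 (SE 0.22) and Lamb1 by 1.51 (SE 0.18). That list summed to 3386 to 3518 CPM in DuxKO iTSC, 1908 and 1980 CPM in C1 libraries 4 and 5 and 997 to 1237 CPM in the other NaB iTSC libraries. Its median was 1.36, and 1.41 with C1 libraries 4 and 5 only. It also holds matrix genes such as Lamb1, so its rise is no measure of endoderm cells alone. Fibroblast-list genes were higher for 22 of 25 (23 adjusted over the list alone), including Prrx2 by 3.01 and Pdgfrb by 2.80, and summed to 2181 to 2365 CPM in DuxKO iTSC, against 133 to 243 CPM in C2 and C1 libraries 1 to 3 and 1457 and 1487 CPM in C1 libraries 4 and 5. Interferon-response genes were higher for 7 of 21, with Irf7 up by 2.78 and Ifit2 by 2.51. That list summed to 730 and 760 CPM in DuxKO iTSC, 507 to 751 CPM in C2 and C1 libraries 1 to 3, and 104 and 113 CPM in C1 libraries 4 and 5. Its median was 0.97, but 0.73 with C1 libraries 1 to 3 only and 1.97 with C1 libraries 4 and 5 only.

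FGF/ERK feedback genes were lower for 8 of 18 and higher for 2, with the feedback inhibitors Spry4 at −2.85 (SE 0.09), Spred2 at −1.35 and Spry2 at −1.13. Cell-cycle genes of G2/M were lower for 6 of 22 and higher for none, with Bub1 at −1.72 (SE 0.14) and Top2a at −1.04 (SE 0.08). Primed epiblast genes were lower for 6 of 15 (7 adjusted over the list alone) and higher for 2, with Zic2 at −3.64 (SE 0.12), Zic5 at −3.34 (SE 0.12) and Dnmt3b, a methyltransferase, at −1.53 (SE 0.07). In the pluripotency list 8 of 30 were lower and 3 higher, with Nr0b1 at −2.63 and Utf1 at −1.78 and a list median of −1.29, but −0.29 with C1 libraries 4 and 5 only, and among somatic germ-layer genes 4 of 16 were lower and 2 higher. Imprinted genes were higher for 14 of 35 and lower for 4, with Plagl1 up by 3.36 and Igf2r at −1.34. The log-scale value for Cdkn1c was 1.53, but DuxKO iTSC had 31.1 CPM, line C1 92.9 CPM and line C2 1.25 CPM.

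Among the large rises were the connexin Gjb2 (6.73), Arhgef6 (5.96) and Serpinb9g (5.50). The keratin Krt14 was at 29.2 against 0.400 CPM, and the log-scale values of Krt14 and Ctsj are no exact folds, since Ctsj was at 0 in line C2 and Krt14 at 0 in 2 of its 3 libraries. The largest falls were in Sox3 (−5.96), the glutamate receptor gene Grin1 (−4.71), Dlgap1 (−4.46), St8sia5 (−4.40) and Zic3 (−4.31).

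Of 16655 genes edgeR called 4036, with 2704 higher and 1332 lower. Adjusted camera p values were 1.25e-13 for G2/M, 4.06e-06 for primed epiblast and 0.00612 for imprinted genes (0.0361, 0.0361 and 0.0450 as the adjusted p with an estimated correlation). They were 1.28e-05 for fibroblast (0.600 as the adjusted p with an estimated correlation), 5.28e-04 for FGF/ERK feedback (0.0881), 0.00339 for differentiated trophoblast (0.391), 0.0153 for primitive endoderm (0.0799), 0.0443 for interferon response (0.665), 0.0229 for pluripotency (0.665), 0.0229 for somatic germ-layer genes (0.0881), 0.00671 for glycolysis, which was lower (0.629), and 0.0229 for mitochondrial messages, which were higher (0.629). With the line as the unit edgeR called 0 genes, with 5270 at an unadjusted p under 0.05, and DESeq2 on the same sums called 1953. Since there was 1 knockout line, a difference between lines and an effect of Dux cannot be told apart, and Cdkn1c turned to −0.90 with the 8 libraries weighted equally and to −0.54 with the line as the unit.

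Against bTSC, several core factors were lower in DuxKO iTSC, while Gata3, at −0.43 (SE 0.15), was not called. Eomes was at −1.84 (SE 0.08), Cdx2 at −1.59 (SE 0.11), Elf5 at −1.58 (SE 0.28), Tfap2c at −1.39 (SE 0.09), Esrrb at −1.70 (SE 0.12) and Sox2 at −1.98 (SE 0.42). Cell-cycle genes of G2/M were lower for 15 of 22 and higher for none (15 adjusted over the list alone), with Top2a at −1.57 (SE 0.10), Ccnb1 at −1.19 (SE 0.07) and Birc5 at −1.31 (SE 0.08). Fibroblast-list genes differed for 1 of 25, which was higher. Phlda2 was at −9.07 (SE 0.54), p53 targets were higher for 9 of 24, with Trp53inp1 up by 1.49 (SE 0.13), and imprinted genes were higher for 17 of 35 and lower for 6 (18 and 7 adjusted over the list alone). Hspa1a, a heat-shock gene, rose by 4.47 (SE 0.41).

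Of 16655 genes edgeR called 3310, with 2029 higher and 1281 lower. The adjusted camera p was 1.74e-21 for G2/M (0.0143 as the adjusted p with an estimated correlation), 9.38e-04 for p53 targets (0.684), 0.0308 for imprinted genes (0.109), 0.0375 for TSC self-renewal (0.684), 0.00132 for primed epiblast, with 5 of 15 called lower but a median of 0.12 (0.109), 0.0180 for germline genes, which were lower (0.684), and 0.0154 for sterol synthesis, which was higher (0.684). The share of called genes that were higher, 61.3%, turned to 47.9 and 49.7% without bTSC library 1 or 2. Each of these lines was 1 line, so the p values measured the spread between libraries, not between independent lines. An effect of Dux cannot be told apart from other differences between these lines, such as those in Eif2s3y and Xist.

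**Figure D3:**
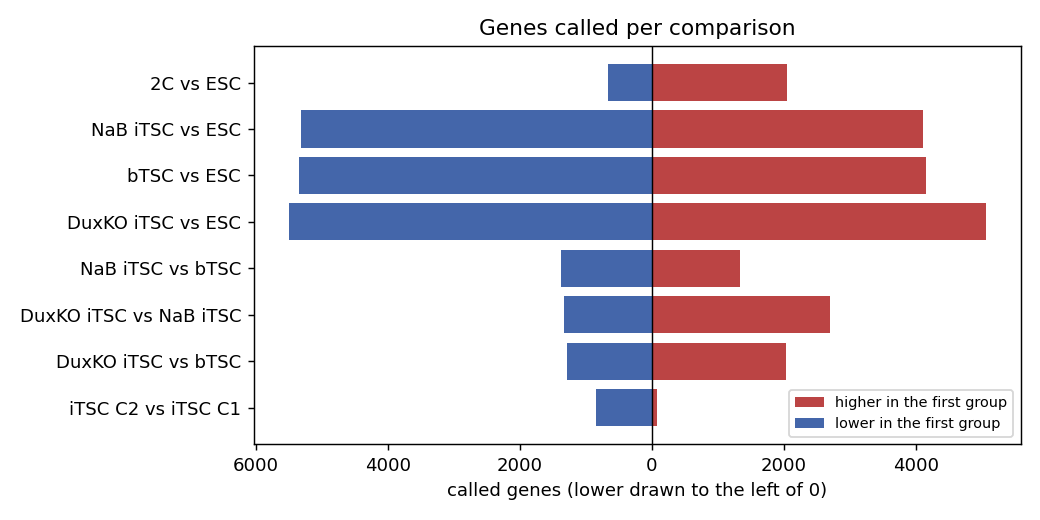
Number of genes called per comparison, with genes higher in the first group drawn to the right of 0 and genes lower in it to the left. The comparisons with ESC call 9422 to 10562 genes for the TSC groups, and C2 against C1 calls 80 higher and 850 lower, or 902 and 1789 with C1 libraries 4 and 5 only.

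The NaB-induced lines C2 and C1 differed by less than the fold threshold in their core factors and by more in imprinted genes. Cdx2 (0.02, SE 0.08), Eomes (0.43, SE 0.06), Elf5 (0.27, SE 0.20), Tfap2c (0.50, SE 0.06), Esrrb (0.54, SE 0.09), Gata3 (−0.13, SE 0.11) and Sox2 (0.35, SE 0.29) were below the fold threshold. Sox2 was at 215 to 223 CPM in C2, 207 to 234 CPM in C1 libraries 1 to 3 and 90.3 and 102 CPM in C1 libraries 4 and 5, and with libraries 4 and 5 only it was called at 1.17 (SE 0.06). Of 35 imprinted genes 16 were lower in C2 and none higher (18 adjusted over the list alone), with a list median of −1.33, or −0.79 with C1 libraries 4 and 5 only. Cdkn1c was at 1.25 ± 0.220 CPM in C2 and 92.9 ± 18.7 CPM in C1, Phlda2 at 0.0760 and 14.1 CPM, Meg3 at 4.55 and 84.8 CPM, and Plagl1 at 1.64 and 14.5 CPM. Each was lower in every C2 library than in every C1 library.

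Some members of other lists were also lower in C2. Differentiated trophoblast genes were lower for 7 of 28 (16 adjusted over the list alone), with Nrk at −2.20 (SE 0.37). Fibroblast-list genes were lower for 8 of 25 and primitive endoderm genes for 6 of 23, with Tagln at −2.75 (SE 0.14) and Fst, an activin antagonist, at −4.19 (SE 0.15). The medians of the differentiated trophoblast and fibroblast lists were −3.32 and −2.50, but −0.64 and −0.23 with C1 libraries 1 to 3 only, −0.69 and −0.24 with the replicate block and −4.43 and −3.45 with C1 libraries 4 and 5 only, so both rested mostly on C1 libraries 4 and 5, while Tagln was lower in every C2 library than in every C1 library. The median of the primitive endoderm list was −0.46, or −0.26 with C1 libraries 1 to 3 only. The medians of the sterol synthesis and glycolysis lists were 0.26 and 0.14, or 0.16 and 0.03 with C1 libraries 1 to 3 only or the replicate block and 0.42 and 0.46 with C1 libraries 4 and 5 only, with no member called higher, 1 sterol synthesis gene called lower, and an adjusted p of 0.576 and 0.730 with an estimated correlation. Klf2 was at −2.32 (SE 0.13), Klf4 at −2.33 (SE 0.36) and Tbx3 at −1.52 (SE 0.16), and 7 of 30 pluripotency genes were lower (14 adjusted over the list alone). With C1 libraries 4 and 5 only, the pluripotency list turned to 0.58, Dppa5a to 1.84 (SE 1.32) and Nanog, at −5.40 (SE 1.73) and not called with all libraries, to 3.29 (SE 0.94). Nanog held 0 and 2 counts in these C1 libraries, under the floor, against 24, 17 and 11 counts in C2, so 3.29 is no exact fold. Dppa5a was at 95.4 to 155 CPM in C1 libraries 1 to 3, at 0 and 0.0454 CPM in libraries 4 and 5 and at 0.136 to 0.176 CPM in C2. Its fall therefore rested on C1 libraries 1 to 3, as did those of Pou5f1, Lefty2 and Ifitm1. Lefty2 was at 29.5 to 34.8 CPM and Ifitm1 at 32.2 to 35.9 CPM in these libraries, and at most at 0.0908 and 0.590 CPM in libraries 4 and 5. The largest falls were in Dppa5a (−8.92), Pou5f1 (−8.86), Ifitm1 (−8.32), Lefty2 (−7.67) and Phlda2 (−7.47), and the largest rises in Jakmip1 (2.13), Bglap3 (2.08), Cd93 (1.76), Lxn (1.75) and Stac2 (1.47).

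By edgeR 930 of 16655 genes were called. Adjusted camera p values were 1.80e-18 for imprinted genes and 1.03e-04 for primitive endoderm (1.09e-04 and 0.0162 as the adjusted p with an estimated correlation), 5.86e-08 for differentiated trophoblast (0.0840), 1.38e-08 for fibroblast (0.576), 0.00378 for pluripotency (0.730), 4.29e-05 for sterol synthesis (0.576) and 0.00832 for glycolysis (0.730). The count was 500, 493 and 508 without C2 libraries 1, 2 and 3, 1522 with C1 libraries 1 to 3 only and 2691 with C1 libraries 4 and 5 only, of which 902 were higher and 1789 lower, and 1513 with the replicate block. That block also sets C1 libraries 4 and 5 aside, so it largely repeats the fit with C1 libraries 1 to 3 only. The calls of Pou5f1, Dppa5a and Lefty2 ended when C1 library 1, 2 or 3, any C2 library or the low-count filter was left out, with values between −8.91 and −8.51, −9.04 and −8.48, and −8.06 and −7.13, and those of Ifitm1 and Jakmip1 ended when any C2 library or the low-count filter was left out, between −8.71 and −7.78 and between 2.1 and 2.18.

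Chromosome-wide levels were compared with line C2 as the median difference of log2(CPM + 1) over the protein-coding genes of a chromosome at a mean of 5 CPM or more, relative to the median of all autosomes. In bTSC these were 0.39 for the 582 genes of chromosome 8 and 0.38 for the 864 genes of chromosome 11. In DuxKO iTSC the 577 genes of chromosome 1 were at 0.44. Chromosome 14 was at 0.21 in bTSC and 0.34 in DuxKO iTSC.

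**Figure D4:**
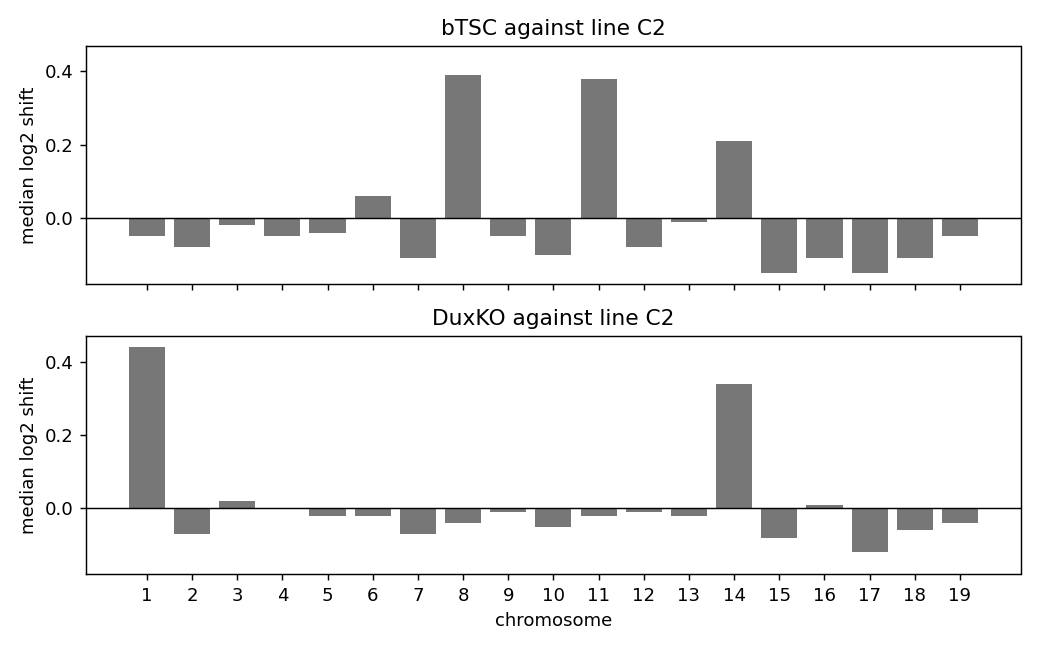
Median difference of log2(CPM + 1) from line C2 for each autosome, relative to all autosomes, in bTSC (top) and DuxKO iTSC (bottom). Chromosomes 8 and 11 stood at 0.39 and 0.38 in bTSC and chromosome 1 at 0.44 in DuxKO iTSC, while the other autosomes apart from chromosome 14 lay between −0.15 and 0.06 in bTSC and between −0.12 and 0.02 in DuxKO iTSC.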

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

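The tests of leaked reads and of admixed fibroblasts were chosen only after the result was seen, as were the fits that kept a subset of the C1 libraries. Within line C1, 4 of 120 gene measures had 1 library far from the other 4, and chance alone gives about 1 in 20. Bc1 was at 0.0486 CPM in library 2, which is 1 count, and at 0 in the others. Zic5 was at 111.5 CPM in library 2 against 91.2 to 96.3 CPM, and Rsad2 at 3.93 CPM against at most 1.104 CPM. Rhox9 was at 14.4 CPM in library 5 against 7.54 to 9.01 CPM.

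Lines C2 and C1 differed in 930 genes. Of the 56 splits of their 8 libraries into 5 and 3, only the real split, 1, called as many. The libraries were not interchangeable. Correlations of log2(CPM + 1) were 0.993 or more within C1 libraries 1 to 3, C1 libraries 4 and 5, and C2, and at most 0.97 between them. The rank of the real split therefore did not test chance for a difference between lines. The highest other split called 901. That split set C1 libraries 1 to 3 against the rest, which points to a structure inside line C1. The count was 1522 with C1 libraries 1 to 3 only and 2691 with C1 libraries 4 and 5 only, and 500, 493 and 508 without C2 libraries 1, 2 and 3.

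Among imprinted and placental genes, the log2 difference of C2 minus C1 was −7.47 for Phlda2, −6.21 for Cdkn1c, −4.22 for Meg3, −3.16 for Plagl1, −2.20 for Nrk and −1.07 for Hand1. Hand1 depended on C1 libraries 4 and 5, since it was under the fold threshold at −0.74 with C1 libraries 1 to 3 only, at −0.73 with the replicate block, and at −0.95 and −0.96 without C1 library 4 or 5. For keratins and other trophoblast genes it was −4.97 for Krt14, which had 1 count in C2 (C1 exceeded C2 by a ratio of 40.9, 95% counting interval 7.05 to 1646), −1.30 for Krt7, −2.46 for Rhox9 and −3.28 for Serpinb9g. It was −1.96 for Dab2, −1.61 for Ifit2 and −3.11 for Ednra.

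The pluripotency genes Pou5f1, Klf2 and Tbx3 differed between the lines by −8.86, −2.32 and −1.52, and Pou5f1 was at 195 to 251 CPM in C1 libraries 1 to 3 and at or under 0.0908 CPM in libraries 4 and 5. Over 55 ESC-specific genes the median level in libraries 1 to 3 was 13.8, 11.5 and 8.31% of ESC. Admixed ESC may explain this, and in that case few of these genes would lie far under the median ratio. The share under 0.25 of it was 21.8, 21.8 and 16.4%, on both sides of the bound of 20% set in advance, so this share decided nothing. Genes under it included named ones such as Fam166a, at 0 in libraries 1 to 3. They also included model-name rows such as Gm28635 and Gm45717, at 0 in every C1 library. Since ESC and TSC libraries may have been counted differently, the absence of such rows is not held against admixed ESC. Reads leaked from the ESC libraries would keep all genes in 1 ratio, as would admixed ESC in the same state as those libraries. At most 70.8% of the 48 genes without model names were within 2-fold of their median. Mylpf was at 1.39 to 2.13% of ESC, Pou5f1 at 19.03 to 24.4% and Lefty2 at 58.2 to 68.5%. These values argue against leakage as the whole source, and equally against admixed ESC in that state. Both readings assume that the ESC and TSC libraries were counted alike. The abundant row CT010467.1, at most 0.158 of the median ratio, did not settle the question of leakage. Admixed ESC in another state and a share of cells in line C1 that kept ESC genes were not tested and stay open.

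The fibroblast-list genes Pdgfrb, Tagln, Acta2, Prrx2 and Col5a1 differed between the lines by −2.66, −2.75, −2.73, −2.36 and −1.59. Over 23 genes the median level relative to DuxKO iTSC was 69.2 and 66.4% in C1 libraries 4 and 5 and 60.5 and 62.0% in bTSC, against 6.12 to 9.24% in C1 libraries 1 to 3 and 5.24 to 5.64% in C2, and Col1a1 was at 155 and 143 CPM in C1 libraries 4 and 5 and 197 and 219 CPM in DuxKO iTSC. A candidate explanation is admixed fibroblasts of 1 kind, which would keep these genes in 1 ratio. In C1 libraries 4 and 5 and in bTSC 0% of the 23 genes were over 4-fold from the median ratio, as admixed fibroblasts of 1 kind need, but the test parts weakly, since C2 gave 4.35% and ESC 73.9%. Hprt and Xist, picked after their values had been seen, were also higher in C1 libraries 4 and 5. Hprt was at 12.9 and 13.1 CPM there and 25.6 and 25.5 CPM in DuxKO iTSC, and Xist at 115 and 118 and at 291 and 345 CPM. They were at most at 1.93 and 15.9 CPM in the other NaB iTSC libraries. In bTSC both were higher than in DuxKO iTSC, but the fibroblast list was lower. Since bTSC were a line of another origin, this says little about line C1 or DuxKO iTSC. Expression of the fibroblast-list genes by the TSC themselves would have to extend to Hprt and Xist, was not tested and stays open. The labels name no sort that would remove fibroblasts from the TSC.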

How the results depend on the processing

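The fits that removed ribosomal RNA rows, kept protein-coding genes only or kept a subset of the C1 libraries were chosen only after the result was seen. In these fits 875 tests of named genes had the same direction and side of the threshold, 7 lost the call, 9 gained it and 7 changed direction, and for gene lists these were 382, 14, 37 and 4. Among the other settings, leave-one-out apart, the counts were 1574, 126, 12 and 5 for genes and 868, 86, 68 and 2 for lists. With a library left out they were 2065, 56, 3 and 2 for genes and 971, 16, 36 and 0 for lists. Of the list tests, 1132 were past the threshold with neither setting and were given no direction, and in 103 of these the direction of camera changed. Without a fold threshold, which calls more genes by construction, the counts were 8181 for 2C-like cells against ESC, 14242 for NaB iTSC against ESC, 7305 for NaB iTSC against bTSC, 9206 for DuxKO iTSC against NaB iTSC, 7377 for DuxKO iTSC against bTSC and 2239 for C2 against C1, of which 885 were higher and 1354 lower. With the line as the unit, which leaves fewer samples, edgeR called 4897 genes for NaB iTSC against ESC, and 0 and 0 for NaB iTSC against bTSC and DuxKO iTSC against NaB iTSC, where 3979 and 5270 had an unadjusted p under 0.05 and DESeq2 called 1033 and 1953. With the replicate block the counts were 2759, 9497, 10002 and 10966 for 2C-like cells, NaB iTSC, bTSC and DuxKO iTSC against ESC, 3883, 4866 and 4401 for the 3 comparisons among TSC groups, and 1513 for C2 against C1. Where line C1 was in the fit, the block also set C1 libraries 4 and 5 aside, so it is no test of pairing alone. Between lines C2 and C1, 0 of 3 C2 libraries correlated best with the C1 library of their number, and over all pairs of groups the correlation of libraries with the same number ran from −0.09 to 0.25 across 9536 genes, so pairing elsewhere was not excluded. With the estimated correlation 7 list tests stayed past the threshold. For C2 against C1 the count was 1522 with C1 libraries 1 to 3 only and 2691 with C1 libraries 4 and 5 only, and 493 to 1237 in leave-one-out. The other leave-one-out ranges were 2284 to 2897 for 2C-like cells against ESC, 8854 to 9478 for NaB iTSC, 8767 to 9041 for bTSC and 9851 to 10267 for DuxKO iTSC against ESC, 2033 to 3296 for NaB iTSC against bTSC, 3213 to 4518 for DuxKO iTSC against NaB iTSC and 2595 to 2679 for DuxKO iTSC against bTSC. A lone library left in a group was assumed to vary like the other groups.

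Values that changed direction were as follows, and the cause was not tested beyond which libraries a setting left out. Sox2 was at −0.05 in 2C-like cells against ESC with no low-count filter. In C2 against C1 the replicate block gave 0.23 for primed epiblast, −0.61 for interferon response, 0.02 for Gata3 and −0.01 for Sox2, and C1 libraries 1 to 3 only gave 0.22, −0.63, 0.02 and −0.01. These are not separate checks, since the block also sets C1 libraries 4 and 5 aside. With C1 libraries 4 and 5 only, NaB iTSC against bTSC gave 0.08 for Elf5 and −1.29 for Nanog, and C2 against C1 gave 0.58 for pluripotency, −0.17 for p53 targets, 1.84 for Dppa5a, −0.14 for Elf5 and 3.29 for Nanog. Nanog and Dppa5a held at most 2 and 1 counts in these C1 libraries, so their values are no exact folds. Cdx2 in C2 against C1 ran from −0.04 to 0.05 in leave-one-out. Cdkn1c in DuxKO iTSC against NaB iTSC was at −0.90 with the 8 libraries as 1 group and −0.54 with the line as the unit. The median of all genes moved by −0.143, −0.119 and −0.121 for NaB iTSC, bTSC and DuxKO iTSC against ESC with DESeq2 size factors, by −0.156, −0.139 and −0.212 with protein-coding genes only, by 0.125 for NaB iTSC with the line as the unit, and by −0.121 for 2C-like cells without a filter. Depth limits genes near the floor, which was highest, at 0.731 CPM, in C1 library 4.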

Other observations

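The genes described here were chosen after their values were seen, and the tests of admixed fibroblasts and of chromosomes in parts were chosen only after the result was seen. H19, an imprinted noncoding RNA, was at 2944 and 2966 CPM in DuxKO iTSC and at 379 and 388 CPM in bTSC. In line C1 it was at 2122 and 2152 CPM in libraries 4 and 5 and at 803 to 959 CPM in libraries 1 to 3, and in line C2 at 243 to 258 CPM. The keratin Krt8 was at 3562 and 3191 CPM in DuxKO iTSC and at 634 to 707 CPM in bTSC. Prl3d1, a placental lactogen of giant cells, was at 17.3 and 24.7 CPM in C1 libraries 4 and 5, at 0.389 to 1.03 CPM in C1 libraries 1 to 3 and at 9.21 and 9.82 CPM in DuxKO iTSC. Slc2a3, a glucose carrier, was at 2180 to 2295 CPM in C1 libraries 1 to 3 and at 624 and 638 CPM in libraries 4 and 5. Brachyury, listed as T, was at 38.1 to 44.3 CPM in C1 libraries 1 to 3 and at 0.227 to 0.244 CPM in libraries 4 and 5.

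The Y-linked gene Eif2s3y was at 50.1 and 53.2 CPM in ESC, 46.8 to 56.6 CPM in lines C1 and C2, 40.04 and 41.9 CPM in DuxKO iTSC and 1.62 and 2.08 CPM in bTSC. Other Y-linked genes differed more between DuxKO iTSC and lines C1 and C2. Ddx3y was at 14.8 and 14.2 against 51.1 to 65.8 CPM, and Uty at 6.04 against 16.3 to 36.3 CPM. Kdm5d went the other way, at 4.58 and 3.54 against 0.0458 to 3.405 CPM. Xist was at 818 and 1214 CPM in bTSC, 291 and 345 CPM in DuxKO iTSC, 115 and 118 CPM in C1 libraries 4 and 5 and at most 15.9 CPM in the other NaB iTSC libraries. Hprt, a purine salvage gene, was at 78.2 and 97.6 CPM in bTSC, 25.6 and 25.5 CPM in DuxKO iTSC, 12.9 and 13.1 CPM in C1 libraries 4 and 5 and at most 1.93 CPM in the other NaB iTSC libraries. Its level in ESC was 0.3125 and 0.453 CPM. Interferon-response genes summed to 104 and 113 CPM in C1 libraries 4 and 5 and to 597 to 751 CPM in C1 libraries 1 to 3. The 1583 rows named as pseudogenes summed to 13090 to 17600 CPM in ESC and 2C-like libraries and to 2379 to 3476 CPM in TSC libraries, so a difference in alignment or counting between these sets is not excluded.

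A hypothesis for the chromosome-wide levels is extra copies of whole chromosomes in part or all of the cells. On chromosomes 8 and 11 in bTSC and 1 in DuxKO iTSC, 100% of 10-Mb bins were above the autosome median. The median over uncalled genes was at least 0.788 of that over all genes. A few genes can hardly move a median over 577 to 864 genes, so this ratio was no test of a few strongly changed genes. On chromosome 14 at most 58.3% of bins were above the autosome median, so extra copies of the whole chromosome are argued against there. The lowest ratio was 0.364, but a few genes can hardly move a median over 357 genes either, so the cause of this shift stays open. Over all 5 shifts the lowest values were 33.3% and 0.364, which decided neither extra copies nor a few strongly changed genes. Admixed fibroblasts may also carry extra copies, but C1 libraries 4 and 5 had at most 0.218 of the DuxKO shift on chromosomes 1 and 14, which argues against 1 shared kind.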
